A study of Mus musculus with 4 samples.

How the data were processed

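RNA was sequenced from 3 libraries of cultured mouse olfactory horizontal basal cells (HBCs) and 1 library of sorted mouse respiratory basal cells (RBCs). Per the labels, RNA was prepared with a column microprep kit and libraries with standard Illumina methods. The submitters' processing notes name STAR, Cufflinks 2.2.1, Cuffnorm and the mouse genome build mm9, without a role or order. The gene annotation, strand setting and filters are not given in the sources used here. The 4 libraries share 1 deposited table with 1 column each, and columns were matched to samples by their names and the sample titles.

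The authors deposited values named FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), 1 per gene symbol and library. The values were examined before any test. In genes with all values below 4, 13.8% to 29.6% of the genes measured in a given pair of libraries had a ratio within 2% of 1. Among windows of that width between ratios of 0.5 and 2, the fullest was centred between 0.980 and 1.01 in each of the 6 pairs. In the pair with the weakest excess it held 14.2% of genes, and the fullest window more than 5% away from 1 held 10.9%. A single read thus appeared to be worth about the same value in every library, while the column sums differ, so no division by the depth of each library was visible. In 764 such genes with a single transcript in GENCODE M21, the smallest value times transcript length in kilobases had a median of 1.26, and 55.9% of these products lay between 0.8 and 1.5. The deposited FPKM values were therefore taken to carry each library's depth, which the sources used here do not state, whereas the planned test assumed that depth had been removed. Values were divided by 1 factor per library before the test: the median ratio to the geometric mean over the 11134 genes at 10 or more in all 4 libraries (0.843, 1.05 and 1.07 for HBC libraries 1, 2 and 3 and 1.06 for the RBC library). This scaling was chosen after the values had been examined, and the planned use of values as deposited was kept as an alternative. Counts are not part of the table and depth in reads is unknown, so no counting interval is given.

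A gene was tested when the mean of the HBC mean and the RBC value was at least 1, which left 16440 of 23281 genes. Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Fold changes on the log2(value + 1) scale understate the change of low genes, and folds in the text are ratios of scaled values. The variance came from the 3 HBC libraries alone (2 residual degrees of freedom), so the p-values assume that the lone RBC library varies as they do, and they measure only the spread between these libraries. Genes listed at 0 in all 3 HBC libraries have no spread, and no p-value is printed for them. All 1256 of them that were tested were called, because the filter admits such a gene only at an RBC value large enough to be called. Their calls are thus no test, but they are counted as called and enter the tests of gene lists. A value of 0 can be a failed estimate: Hmgcs1, a gene of sterol synthesis in most cells, was listed at 0 in all 4 libraries, and Gapdh was at 9.01 to 57.4. No fold is given against a group listed at 0 or near the worth of a single read.

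The procedure was tested on simulated data with the HBC libraries' levels and spread and 200 changed genes (13724 genes tested). It called 55.4% of genes changed 2-fold, 90.6% of those changed 4-fold and 98.5% of those changed 8-fold, and 0 of 13530 unchanged genes. An estimate below 2-fold is never called, which limits the share at 2-fold. Directions were drawn at random and genes averaging below 1 in HBC libraries were left out. The simulation thus does not test scaling under mostly one-way change, or calls of genes at 0 in the HBC libraries. With an extra SD of 0.3 or 0.6 (natural log scale) in the lone library, 3.21% and 24.3% of unchanged genes were called.

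Before the data were examined, 28 gene lists with 558 entries were fixed. They cover basal identity, olfactory transcription factors, globose basal cells, olfactory neurons, sustentacular cells, Bowman's glands, ciliated, secretory, squamous, tuft and ionocyte cells, and leukocytes, fibroblasts, endothelium, smooth muscle, glia, erythrocytes, and melanocytes with skeletal muscle. The rest cover the cell cycle, the Notch, Wnt, retinoid and TGF-beta pathways, interferon, inflammatory and immediate early genes, glycolysis, cholesterol synthesis and xenobiotic defence. Of the entries, 546 matched by symbol, 7 by an older or alternative symbol and 5 were not listed. Only 5 genes stood in more than 1 list. In the HBC libraries, 5 of 24 leukocyte, 4 of 18 fibroblast and 1 of 14 endothelial genes averaged 10 or more. Lists were tested with camera (preset correlation 0.01), adjusted over the lists, with camera's estimated correlation and fry as alternatives. With an estimated correlation camera uses the 2 residual degrees of freedom. With the preset correlation its degrees of freedom come from the number of genes, so very small p-values can arise with 1 RBC library.

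Genes were named by a rule fixed at the same time: the 12 largest changes in each direction among called genes with a higher-group mean of at least 10, leaving out small RNA, Gm-numbered, Rik, pseudogene, Xist and Y-linked symbols; in each list the 2 largest called changes in each direction; and genes fixed by name whatever their result. Some of these genes are not reported here. Symbols are as the table gives them. The reference annotation available is for GRCm38 and the notes name mm9, so no coordinates are given. As a check for a library deposited more than once, the HBC libraries were compared over 8388 genes: no value was identical in a pair, and chi-square per gene was at least 2.24 if values were read counts. This does not show whether they came from separate cultures or animals.

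Alternatives, fixed likewise, were other pseudocounts (0.1 and 5), other filters, other scalings (equal medians, equal sums, quantile normalization, values as deposited), other variance priors and each HBC library left out. A test against a 2-fold change (treat) and a fit without genes at 0 in all HBC libraries were chosen after seeing the data. Named genes were also refitted with the other filters, equal sums and the robust prior, and lists with a pseudocount of 5, no filter and equal sums, both added after seeing the data. Ranges of adjusted p over the alternatives leave out fry and treat, which test another hypothesis, and the fit without genes at 0. For lists they also leave out other variance priors. Figures were drawn with matplotlib 3.10.9.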

Results

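Horizontal basal cells (HBCs) are the reserve stem cells that line the base of the olfactory epithelium, and respiratory basal cells (RBCs) are the corresponding stem cells of the neighbouring respiratory epithelium. Gene expression was measured by RNA sequencing in 3 libraries of mouse HBCs grown in culture to passage 3 and in 1 library of RBCs. The RBCs were microdissected and sorted for the red reporter TdTomato from a strain that carries a Krt5-driven inducible Cre recombinase, whereas the cultures came from wild-type mice and no sort is given for them. The table listed 23281 genes by symbol. Deposited values summed to 8377230, 10335100 and 10856000 in HBC libraries 1, 2 and 3 and to 9877610 in the RBC library, and 15093, 15308, 15190 and 17713 genes were above 0 in these libraries. The number of reads per library is not given in the sources used here. All values below are depth-scaled FPKM, that is, the deposited values divided by 1 factor per library. Means of the HBC libraries are given with their SD (n = 3), and the RBC value is a single library with no replicate. The labels do not say whether the 3 HBC libraries came from separate animals. Limma's p-values for genes thus measure only the spread between these samples, which may be technical. Camera's p-values with the preset correlation compare the genes of a list with other genes. They take genes as units and do not measure spread between animals.

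The 3 HBC libraries resembled one another far more than any resembled the RBC library. Across the 16440 genes tested, Pearson correlation of log2 values was 0.992 ± 0.000416 (SD over 3 pairs) between HBC libraries and 0.783 ± 0.00130 (SD over 3 pairs) between HBC libraries and the RBC library. Spearman correlation was 0.993 and 0.810. These coefficients are across genes, which are not independent replicates. The most abundant gene was Gsto1, a glutathione transferase, in each HBC library and Bpifa1, a secreted protein of nasal and airway epithelium, in the RBC library, where it took 4.72% of the summed values.

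The design asks how cultured olfactory HBCs compare with respiratory basal cells taken from the animal. In limma's test (adjusted p under 0.05 and a change of at least 2-fold), 5621 genes were higher in the RBC library and 2105 were higher in the HBC libraries. A change of at least 10-fold was seen for 1942 of the former and 289 of the latter. Of the genes higher in RBCs, 1256 were listed at 0 in all 3 HBC libraries. These were all the tested genes of that kind, and the filter fixed their calls in advance. The share of called genes that were higher in RBCs was 72.8%, and it became 55.3% when the medians of the libraries were set equal and 46.3% under quantile normalization. The median log2 change of all tested genes was 0.45. It fell by 0.50 with the medians set equal and fell by 0.54 under quantile normalization, and it was 0.10 higher with equal sums and 0.11 higher with values as deposited. With 1 RBC library, the spread came from the HBC libraries alone (median SD 0.0587 on the log2 scale in genes averaging at least 100), and the RBC library was assumed to vary as little. In simulated libraries that had an extra SD of 0.3 (natural log scale) in the lone library, 434 of 13531 unchanged genes were called, and with an extra SD of 0.6 the number was 3282 of 13498 (24.3%).

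The 12 genes named here in each direction changed most on the log2(value + 1) scale among the symbols that the naming rule covers, and their order on that scale depends on the pseudocount. Bpifa1 was at 7.89 ± 2.60 in HBC libraries and 439407 in the RBC library. The odorant-binding and lipocalin genes Obp1a (99323), Obp2a (34644), Obp2b (19980), Lcn11 (26249) and Lcn3 (9233) and the major urinary protein genes Mup4 (27822) and Mup5 (15536) were prominent in the RBC library and averaged below 1.3 or were listed at 0 in the HBC libraries. Bpifb1 (16650), Serpina3n (16183), Chi3l4 (8240) and Dmbt1 (7831), a mucosal scavenger receptor, completed this group. Towards the HBC libraries these genes included Calcb, a calcitonin-related peptide (23280 ± 883 against 3.67), and the platelet chemokine Ppbp (40681 ± 1576 against 14.8). Olfm4 (6061 ± 330 against 5.16) and the epithelial protease Tmprss11e (1065 ± 66.4 against 0.289) also stood high. The late cornified envelope genes Lce1h (3029 ± 125), Lce1g (915 ± 45.5) and Lce1f (694 ± 75.4), and Krt20 (598 ± 27.6) and Slc25a48 (470 ± 2.69), were listed at 0 in the RBC library. The interferon-inducible genes Pyhin1, Ifi205 and Ifi204 averaged 2217 ± 56.2, 655 ± 56.3 and 1257 ± 124 in HBC libraries and 1.97, 0 and 1.33 in RBCs. The Obp2, Mup, Lce1 and Ifi20x genes have near-identical neighbours, so the split of reads among them is uncertain.

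Genes that mark basal cells were expressed in both groups, and most of those that differed were higher in the RBC library. Of 22 tested basal cell genes, 13 were called higher in RBCs, 2 were called higher in HBCs and 7 were not called. For comparison with this and the other lists, 5621 of all 16440 genes tested were called higher in RBCs and 2105 higher in HBCs. Trp63, the transcription factor that maintains basal stem cells, was 7.88-fold higher in the RBC library (4307 against 546 ± 12.8, limma adjusted p = 0.000127). Keratin 15 was 13.6-fold higher (17199 against 1267 ± 41.5) and keratin 14 was 4.49-fold higher (11645 against 2594 ± 135). The adhesion molecule Icam1 was 29.8-fold higher (1494 against 50.1 ± 5.65), and Dlk2 was 32.6-fold higher (1781 against 54.6 ± 11). Keratin 5, the gene whose promoter drives the Cre recombinase, differed by less than 2-fold (18625 ± 369 in HBCs and 26488 in RBCs), as did Egfr (456 ± 13.5 and 711) and the integrin Itga6 (1284 ± 21.4 and 844). Setting the medians equal took Itga6 past the 2-fold minimum as higher in HBCs (log2 change -1.11). Integrin beta 1 and keratin 17 were 2.41-fold and 2.15-fold higher in HBCs (5952 ± 143 against 2470, and 18006 ± 793 against 8390). Neither reached the 2-fold minimum with quantile normalization (log2 change -0.95 for Itgb1 and -0.86 for Krt17), and Krt17 also with values as deposited (-0.99). As a list, the basal genes did not stand apart from other genes (camera adjusted p = 0.302, and adjusted p = 0.635 with an estimated correlation). The list passed the threshold under quantile normalization (adjusted p = 0.00728) and with the medians set equal (adjusted p = 0.0319), with a range of 0.00728 to 0.635 over the alternatives of this test. In the same RBC library, 46 of 55 tested markers of leukocytes, fibroblasts and endothelium were also called higher.

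**Figure D1:**
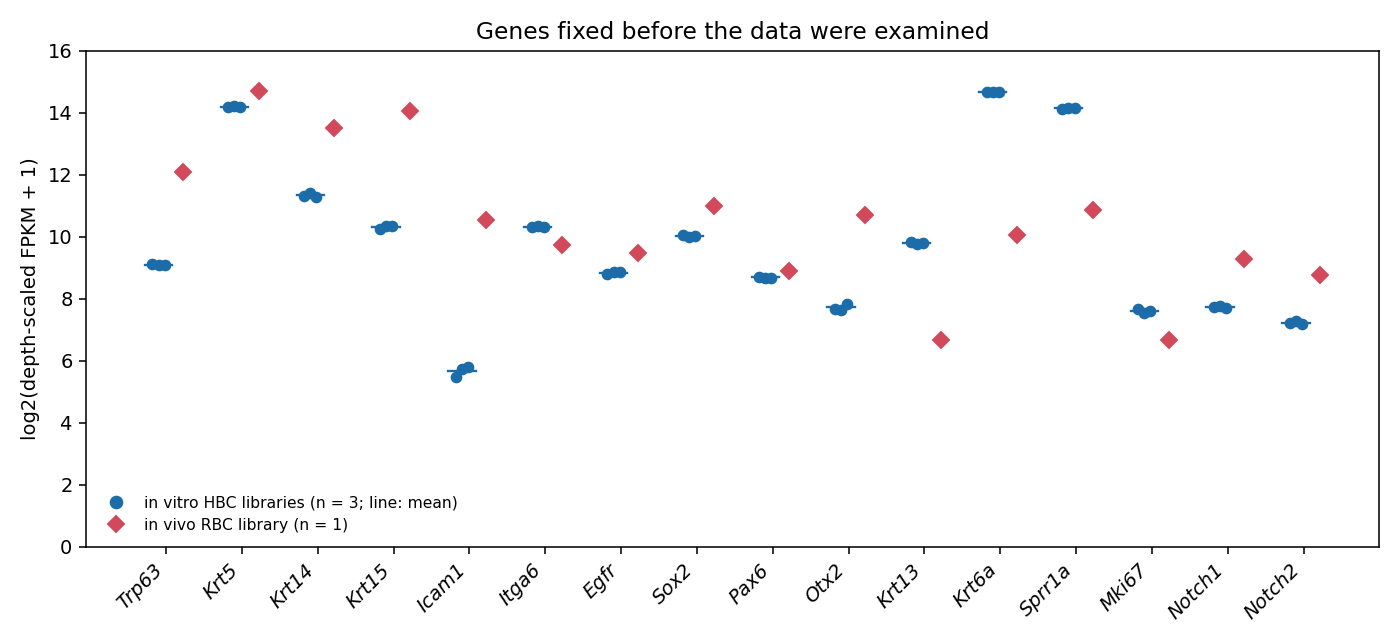
Log2(depth-scaled FPKM + 1) of 16 genes fixed by name in advance, with the genes on the horizontal axis; circles are the 3 in vitro HBC libraries with a line at their mean, and diamonds are the single in vivo RBC library. Trp63, Krt14, Krt15, Icam1 and Otx2 lie higher in the RBC library, Krt13, Krt6a and Sprr1a lie higher in the HBC libraries, and Pax6 and Krt5 differ by less than 2-fold, Pax6 turning direction with the medians of the libraries set equal.

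Most transcription factors of the olfactory placode and epithelium on the fixed list were higher in the RBC library. Of 15 tested, 11 were called higher in the RBC library and 4, among them Pax6 and Sox2, were not called. Pax6 was nearly level (411 ± 6.38 in HBCs and 471 in RBCs), and its direction turned with the medians set equal (log2 change 0.20 against -0.31). Sox2 was at 1039 ± 20.9 and 2040, just under the 2-fold minimum, and passed it under quantile normalization (log2 change 1.28), with values as deposited (1.09) and with equal sums (1.07). Otx2, a homeobox factor of the anterior head, was 8.01-fold higher in RBCs (1680 against 210 ± 14.4). Lhx2 and Dlx3 averaged 0.854 ± 0.708 and 0.129 ± 0.224 in HBCs, values of the order of single reads, and stood at 81.7 and 37.4 in RBCs. The list passed camera's threshold (adjusted p = 0.0185) but not with an estimated correlation (adjusted p = 0.304). In the same RBC library, 46 of 55 tested leukocyte, fibroblast and endothelial markers were higher. Whether basal cells or other cells in the RBC sample carried these transcription factor transcripts was not tested.

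Most tested genes of olfactory sensory neurons were higher in the RBC library. Of 20 tested sensory neuron genes, 19 were called higher in RBCs and 1 was not called (camera adjusted p = 0.000566, and adjusted p = 0.193 with an estimated correlation). The olfactory marker protein gene Omp was 23.6-fold higher (1500 against 63.5 ± 1.94). Stoml3 (965) and the receptor transporter Rtp1 (203) were listed at 0 in all 3 HBC libraries. Of 12 tested genes of globose basal cells and neuronal precursors, 8 were called higher in RBCs and 1, Mybl1, in HBCs (148 ± 3.11 against 28.4). Kit was at 0.622 ± 0.539 in HBCs and 219 in RBCs, and Nhlh1 was listed at 0 in the HBC libraries and at 31.6 in RBCs. The precursor list did not pass camera's threshold (adjusted p = 0.198, and adjusted p = 0.372 with an estimated correlation). In the same RBC library, 46 of 55 leukocyte, fibroblast and endothelial markers were higher. Whether basal cells or other cells in the RBC sample carried the neuron and precursor transcripts was not tested.

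Most tested genes of differentiated airway and olfactory epithelial cells were higher in the RBC library, in which 46 of 55 leukocyte, fibroblast and endothelial markers were higher too. Of 25 tested ciliated cell genes, 24 were called higher in RBCs and 1 was not called (camera adjusted p = 2.85e-05, and adjusted p = 0.193 with an estimated correlation). Foxj1, the master regulator of motile cilia, was 10.4-fold higher (723 against 69.5 ± 3.52), and the dynein light chain Dynlrb2 was at 1556 against 1.98 ± 1.71. The cilium gene 1110017D15Rik was at 704 and was listed at 0 in the HBC libraries. Of 19 tested secretory cell genes, 17 were higher in RBCs, 1 was higher in HBCs and 1, Muc4, was not called (camera adjusted p = 0.00114, and adjusted p = 0.193 with an estimated correlation). Muc4, named after its values were seen, was at 126 ± 5.47 in HBCs and 139.5 in RBCs. Lactoferrin, Ltf, was 6.59-fold higher in HBCs (119163 ± 1162 against 18086). The Ltf call did not hold with values as deposited (limma adjusted p = 0.0733, with a range of 7.77e-06 to 0.0733 over the alternatives). Scgb1a1, the club cell secretoglobin, was listed at 0 in all 4 libraries. Of 14 tested sustentacular cell genes, 12 were higher in RBCs and 2 were not called (camera adjusted p = 0.00222, and adjusted p = 0.193 with an estimated correlation). The olfactory cytochrome Cyp2g1 (3427) was listed at 0 in all 3 HBC libraries, and Sec14l3 was at 0.248 ± 0.247 in HBCs and 7497 in RBCs. Of 10 Bowman's gland genes, 8 were higher in RBCs (camera adjusted p = 0.00460, and adjusted p = 0.216 with an estimated correlation), among them Dcpp1 (3076) and Dcpp2 (1880), both listed at 0 in HBC libraries. In that list 6 members were listed at 0 in a group, and its median log2 change of 6.78 became 3.64 without them. The water channel Aqp5 was 3.69-fold higher in HBCs (20440 ± 583 against 5534). All 14 tested tuft cell and ionocyte genes were higher in RBCs (camera adjusted p = 0.00143, and adjusted p = 0.193 with an estimated correlation). Among them, 5 were listed at 0 in a group. The proton pump subunit Atp6v1b1 was at 1308 against 1.26 ± 1.36 in HBCs. Ascl3 was at 788 against 1.23 ± 2.14, and its call was lost without HBC library 1 (limma adjusted p = 0.0684) or library 2 (0.0657), with a range of 8.51e-05 to 0.0684 over the alternatives. Dynlrb2 lost its call with a pseudocount of 0.1 (limma adjusted p = 0.0573).

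**Figure D2:**
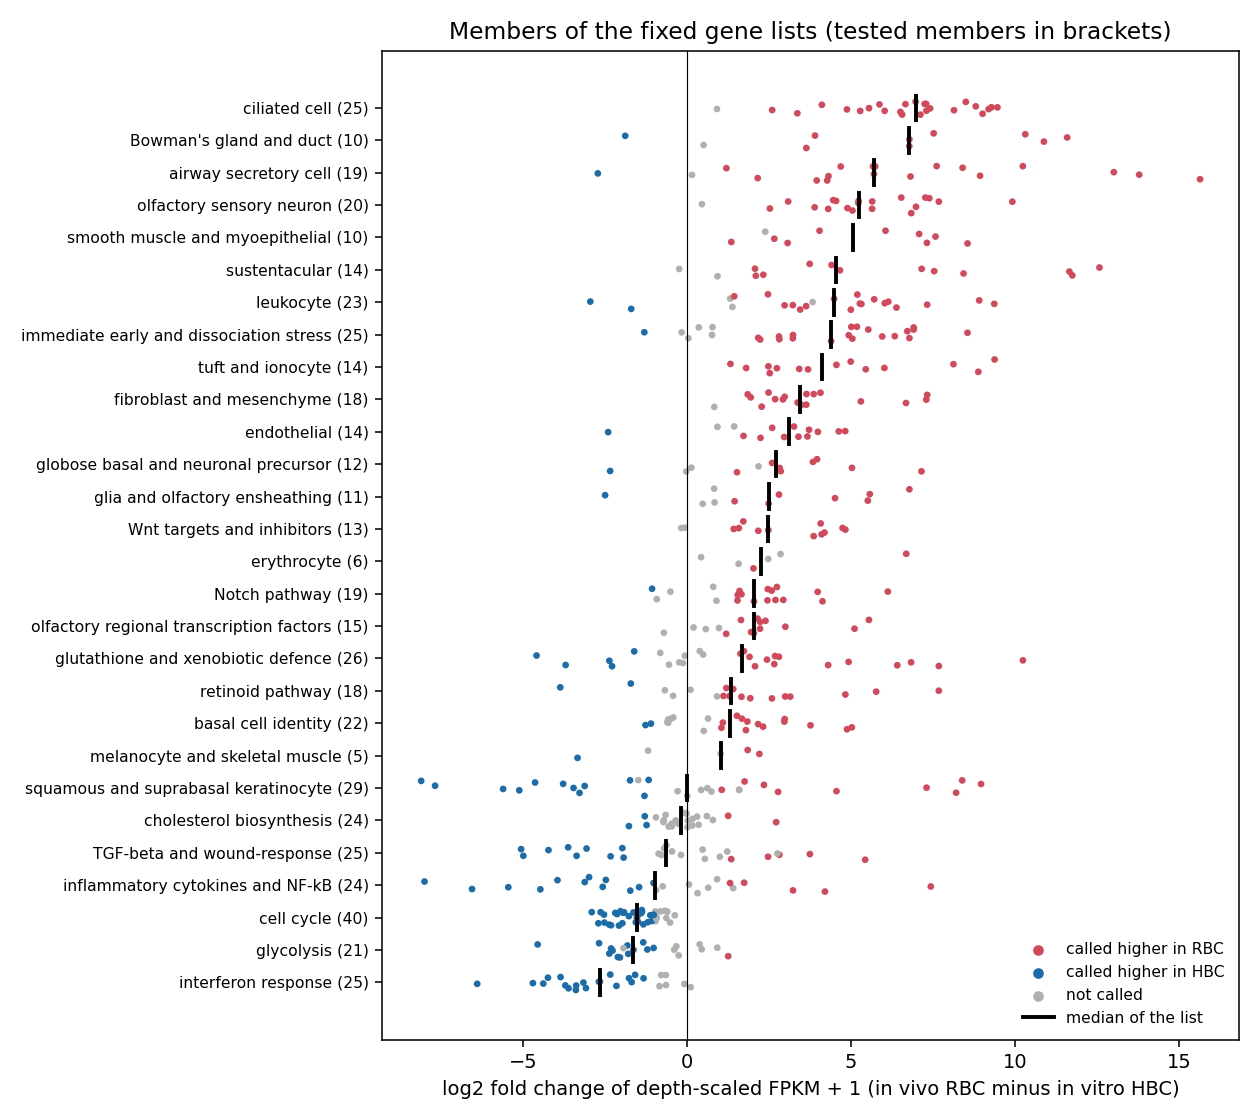
Log2 fold change (in vivo RBC minus in vitro HBC, depth-scaled FPKM + 1) of the tested members of the 28 fixed gene lists on the horizontal axis, with 1 row per list; points are genes, coloured by call, and vertical bars are list medians. The medians of the ciliated, gland, secretory and sensory neuron lists lie to the right of 0, and those of the interferon, glycolysis and cell cycle lists lie to the left.

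Squamous genes divided between the cultures and the RBC library, in which 46 of 55 leukocyte, fibroblast and endothelial markers were higher. Of 29 tested genes of suprabasal and squamous keratinocytes, 12 were called higher in HBCs, 9 higher in RBCs and 8 were not called. Keratin 6a, a keratin of activated keratinocytes, was 24.8-fold higher in HBCs (26111 ± 128 against 1052). The cornified envelope precursors Sprr1a and Ivl were 9.70-fold (18199 ± 204 against 1876) and 310-fold (2498 ± 152 against 8.07) higher in HBCs, and keratin 13 was 8.78-fold higher (886 ± 19.9 against 101). Sprr2f averaged 206 ± 30.6 in HBCs and was listed at 0 in RBCs. In the other direction, Lgals7 was at 889 in RBCs and 1.56 ± 2.70 in HBCs, and Krtdap was at 722 and 3.02 ± 5.23. The call of Lgals7 was lost without HBC library 1 (limma adjusted p = 0.0783) or 3 (0.0736), and that of Krtdap without library 2 (0.120) or 3 (0.118). Over the alternatives, the adjusted p ran from 0.000140 to 0.0783 for Lgals7 and from 0.000958 to 0.120 for Krtdap. The list did not pass camera's threshold (adjusted p = 0.0732, and adjusted p = 0.256 with an estimated correlation). It passed, as higher in HBCs, without the filter on low values (adjusted p = 0.0413) and with values as deposited, where its median log2 change was 0.12 (adjusted p = 0.0272, with a range of 0.0272 to 0.308 over the alternatives of this test). The list's median log2 change was 0.01 (0.52 without the 3 members listed at 0 in a group), its mean was -0.02 and camera's direction was towards HBCs. That median turned to -0.50 with the medians of the libraries set equal and to -0.75 under quantile normalization.

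Most tested cell division and glycolysis genes were higher in the cultures than in the RBC library, in which 46 of 55 leukocyte, fibroblast and endothelial markers were higher. Of 40 tested cell cycle genes, 30 were called higher in HBCs and 10 were not called (camera adjusted p = 1.21e-12, and adjusted p = 0.193 with an estimated correlation), with a median log2 change of -1.51. The mitotic checkpoint kinase Bub1 was 7.93-fold higher in HBCs (126 ± 12.6 against 15.9) and cyclin B1 was 6.62-fold higher (380 ± 26.2 against 57.4). Mki67, the proliferation marker, was at 192 ± 9.37 and 101, just under the 2-fold minimum. It passed that minimum with the medians set equal (log2 change -1.43) and under quantile normalization (-1.63). Of 21 glycolysis genes, 13 were higher in HBCs and 1 in RBCs (camera adjusted p = 6.99e-05, and adjusted p = 0.193 with an estimated correlation). The hypoxia-responsive carbonic anhydrase Car9 was 26.2-fold higher in HBCs (221 ± 13.6 against 8.43), and phosphoglycerate kinase Pgk1 was 6.45-fold higher (2432 ± 214 against 377). The gene called higher in RBCs was Pfkm (313 in RBCs, 131 ± 10.2 in HBCs), which fell under the 2-fold minimum with the medians set equal (log2 change 0.75). Cholesterol synthesis genes differed little, with 3 of 24 called higher in HBCs, 2 higher in RBCs and a median log2 change of -0.18. The sterol oxidase Sc4mol was 3.42-fold higher in HBCs (3228 ± 167 against 944). Insig1 was higher in RBCs (1332 against 558 ± 13.9) but fell under the 2-fold minimum with the medians set equal (log2 change 0.75). The list passed camera's threshold (adjusted p = 0.0349, and adjusted p = 0.398 with an estimated correlation) but not without HBC library 2 (adjusted p = 0.0508) or 3 (0.0592), with a minimum of 5 (0.0838), with equal sums (0.0818) or under quantile normalization (0.480). Its adjusted p ran from 0.00396 to 0.480 over the alternatives of camera's test.

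Most tested interferon-response genes were higher in the cultures than in the RBC library, in which 46 of 55 leukocyte, fibroblast and endothelial markers were higher. Of 25 tested, 19 were called higher in HBCs and 6 were not called (camera adjusted p = 2.35e-09, and adjusted p = 0.193 with an estimated correlation), with a median log2 change of -2.66. Ifit3 was 86.2-fold higher (3824 ± 199 against 44.4), and the antiviral tether Bst2 was 26.1-fold higher (7975 ± 573 against 305). Among 24 inflammatory cytokine and NF-kB genes, 12 were higher in HBCs and 5 in RBCs (camera adjusted p = 0.00757, and adjusted p = 0.195 with an estimated correlation). The epithelial alarmin Tslp was 271-fold higher in HBCs (4846 ± 246 against 17.9) and Il1a was 99.7-fold higher (1650 ± 101 against 16.6). Il1b (171 in RBCs) was listed at 0 in all 3 HBC libraries, and Il6 was at 176 against 9.44 ± 5.45. The Il6 call was lost without HBC library 2 (limma adjusted p = 0.0786) or 3 (0.0765), with a range of 0.000423 to 0.0786 over the alternatives. In the TGF-beta and wound-response list, 9 of 25 genes were higher in HBCs and 5 in RBCs (camera adjusted p = 0.0190, and adjusted p = 0.239 with an estimated correlation). The list did not pass under quantile normalization (adjusted p = 0.0823) or with the medians set equal (0.0875), with a range of 0.00758 to 0.239 over the alternatives of this test. Urokinase, Plau, was 34.0-fold higher in HBCs (1646 ± 81.3 against 48.4) and amphiregulin, Areg, an EGF receptor ligand, was 32.6-fold higher (1214 ± 23.2 against 37.2). Tgfbi was 50.6-fold higher in RBCs (267 against 5.27 ± 1.1). Mmp9 was at 15.8 in RBCs and 0.318 ± 0.550 in HBCs, and its call was lost without HBC library 1 (limma adjusted p = 0.0710) or 3 (0.0663), with a range of 0.000286 to 0.135 over the alternatives.

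Notch and Wnt pathway genes were mostly higher in the RBC library, in which 46 of 55 leukocyte, fibroblast and endothelial markers were higher too. Of 19 tested Notch genes, 14 were called higher in RBCs and 1 in HBCs (camera adjusted p = 0.0272, and adjusted p = 0.304 with an estimated correlation). The receptors Notch1 and Notch2 were 2.92-fold higher each (620 against 212 ± 6.0, and 434 against 149 ± 4.15), and the target gene Hey1 was 71.4-fold higher (2343 against 32.8 ± 3.32). Heyl was at 24.1 against 0.501 ± 0.540, and its call was lost without HBC library 2 (limma adjusted p = 0.0634, with a range of 0.000549 to 0.0737 over the alternatives). The feedback inhibitor Nrarp was 2.10-fold higher in HBCs (218 ± 1.65 against 104), and it did not reach the minimum with values as deposited (log2 change -0.95) or with equal sums (-0.97). Of 13 Wnt targets and inhibitors, 11 were higher in RBCs and 2 were not called (camera adjusted p = 0.0255, and adjusted p = 0.233 with an estimated correlation). The secreted inhibitor Sfrp1 was 28.5-fold higher (3563 against 125 ± 12.8) and Lgr6 was 27.3-fold higher (1138 against 41.7 ± 1.97). In the retinoid list, 12 of 18 genes were higher in RBCs and 2 in HBCs (camera adjusted p = 0.292, and adjusted p = 0.404 with an estimated correlation). That list passed under quantile normalization (adjusted p = 0.0443) and with the medians set equal (0.0341), with a range of 0.0341 to 0.404 over the alternatives of this test. The retinaldehyde dehydrogenases went opposite ways: Aldh1a1 was 208-fold higher in RBCs (8042 against 38.6 ± 4.76), and Aldh1a3 was 14.8-fold higher in HBCs (781 ± 3.36 against 52.7). Tgm2 was 54.6-fold higher in RBCs (10153 against 186 ± 13.8) and Crabp2, a retinoic acid binding protein, was 3.29-fold higher in HBCs (2355 ± 49.6 against 717). In the glutathione and xenobiotic list, 14 of 26 genes were higher in RBCs and 5 in HBCs (camera adjusted p = 0.741, and adjusted p = 0.749 with an estimated correlation). It passed under quantile normalization (adjusted p = 0.0186, with a range of 0.0186 to 0.972 over the alternatives of this test). Fmo1 was at 2148 in RBCs and 0.802 ± 0.336 in HBCs. Gsto1 was 13.0-fold higher in HBCs (197831 ± 4640 against 15203), a call that did not hold with values as deposited (limma adjusted p = 0.0684, with a range of 5.42e-06 to 0.0684 over the alternatives), and Cyp1b1 was 31.7-fold higher in HBCs (95.3 ± 4.21 against 3.00).

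Most tested markers of leukocytes, fibroblasts, endothelium and smooth muscle, and most immediate early genes, were higher in the RBC library. Of 23 tested leukocyte genes, 18 were called higher in RBCs and 2 in HBCs (camera adjusted p = 0.00121, and adjusted p = 0.193 with an estimated correlation). Lyz2 was at 14770 in RBCs and 21.5 ± 3.00 in HBCs, and the MHC class II gene H2-Aa (479) was listed at 0 in HBC libraries. Cd68 was 7.84-fold higher in HBCs (515 ± 42.6 against 65.7), and H2-Eb1 was at 29.2 ± 4.96 against 8.21, a call lost without HBC library 3 (limma adjusted p = 0.0746, with a range of 0.000356 to 0.0746 over the alternatives). Of 18 fibroblast genes, 17 were higher in RBCs and 1 was not called (camera adjusted p = 0.00400, and adjusted p = 0.193 with an estimated correlation), with Dcn at 6902 against 44.0 ± 11.8 and Col1a1 at 361 against 1.27 ± 0.265. Of 14 endothelial genes, 11 were higher in RBCs and 1 in HBCs (camera adjusted p = 0.0205, and adjusted p = 0.231 with an estimated correlation), but the list did not pass under quantile normalization (adjusted p = 0.231, with a range of 0.00564 to 0.231 over the alternatives of this test). Cldn5 (23.7) was listed at 0 in HBC libraries. The calls of Ramp2 (43.0 against 0.924 ± 1.60) and Egfl7 (19.3 against 109 ± 27.1) were lost without HBC library 2 (limma adjusted p = 0.120 and 0.0735), and that of Ramp2 also without library 1 (0.125). Over the alternatives, the adjusted p ran from 0.000456 to 0.125 for Ramp2 and from 4.57e-05 to 0.0735 for Egfl7. Of 10 smooth muscle and myoepithelial genes, 9 were higher in RBCs and 1 was not called (camera adjusted p = 0.0226, and adjusted p = 0.231 with an estimated correlation), with Acta2 at 881 against 1.37 ± 0.338 and Cnn1 (189) listed at 0 in HBC libraries. Of 11 glial genes, 7 were higher in RBCs and 1 in HBCs (camera adjusted p = 0.0349, and adjusted p = 0.404 with an estimated correlation). The glial list did not pass without HBC library 3 (adjusted p = 0.0561), with a pseudocount of 0.1 (0.0561), without the filter on low values (0.0554) or with values as deposited (0.0573), with a range of 0.00566 to 0.404 over the alternatives of this test. Sox10 (109) and Fabp7 (46.5) were listed at 0 in HBC libraries. The erythrocyte list (2 of 6 called higher in RBCs, camera adjusted p = 0.288, and adjusted p = 0.404 with an estimated correlation) did not pass, nor did the melanocyte and skeletal muscle list (2 of 5 called higher in RBCs, camera adjusted p = 0.979, and adjusted p = 0.981 with an estimated correlation). The median of the latter turned from 1.03 to -0.91 under quantile normalization. Of 25 immediate early and stress genes, 19 were higher in RBCs and 1 in HBCs (camera adjusted p = 0.000980, and adjusted p = 0.193 with an estimated correlation), with a median log2 change of 4.39. Fos was 121-fold higher (26583 against 220 ± 6.72), and Egr2 was at 744 against 1.31 ± 1.5, a call lost without HBC library 3 (limma adjusted p = 0.0551, with a range of 4.65e-05 to 0.0551 over the alternatives). Myc was 2.47-fold higher in HBCs (1346 ± 25.2 against 545).

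Over all 28 lists, camera with its preset correlation placed 15 higher in the RBC library and 6 higher in the HBC libraries. With an estimated correlation, 0 of these 21 lists passed in camera, the adjusted p-values running from 0.193 to 0.404, and the unadjusted p was under 0.05 in 4 of the 28 lists. Fry, which tests whether a list's genes move one way without comparing them with other genes, placed 20 lists higher in RBCs and 8 higher in HBCs. Counts adjusted over the list alone equalled those over all genes tested in 27 of the lists. In the melanocyte and skeletal muscle list, 2 genes rather than 1 were higher in HBCs when adjusted over the list alone. Tissue of origin, culture, the sort stated for RBCs and mouse strain all changed together between the groups. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, chosen after their values were seen, were listed at 0 in each HBC library and at 37.7 to 187 in the RBC library. Xist was at 1297 ± 109 in HBC libraries and 1563 in the RBC library, which thus held Xist and Y-linked transcripts together. The sexes of the animals may therefore have differed between the groups too, but a plain contrast of males with females is not shown. No difference can be assigned to one of these factors.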

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

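The scaling used for the reported values, the test against a 2-fold change, the fit without genes at 0 in all 3 HBC libraries and some settings for named genes and lists were chosen after seeing the data. The reported counts (5621 genes higher in RBCs, 2105 higher in HBCs) stayed within 1.5 times under most alternatives. The exceptions were the scalings by medians set equal (3937 higher in HBCs) and by quantile normalization (3148 higher in RBCs and 3657 higher in HBCs); the cause was not tested. Values as deposited gave 5599 and 1713, the test against a 2-fold change 4164 and 1438, and the fit without genes at 0 in all HBC libraries 4675 and 2169. Leaving out each HBC library gave 4932 to 5012 genes higher in RBCs and 2004 to 2040 higher in HBCs. Of the 7726 called genes, 850 changed sign under quantile normalization and 0 under the other alternatives, and 4970 kept their call under it. Lists placed by camera went from 15 and 6 to 0 and 0 with an estimated correlation, which tests on 2 degrees of freedom, and without 1 HBC library they were 14 to 15 and 5 to 6. Fry gave the retinoid list (median log2 change 1.35) the opposite direction, towards HBCs. Correlation between HBC libraries moved from 0.992 to 0.976 with a pseudocount of 0.1 and to 0.992 without the filter, and it was 0.991 to 0.992 without 1 library. Correlation with the RBC library moved from 0.783 to 0.735 with a pseudocount of 0.1, 0.689 with a minimum of 5 and 0.832 without the filter, and it was 0.782 to 0.784 without 1 library. Among 117 named genes, 12 lost their call when 1 HBC library was left out (adjusted p from 0.0550 to 0.125), and Slc4a1 (-0.11) and Pmel (-0.63) changed direction under quantile normalization. No paired analysis was possible, because the replicate numbers only count samples within a group and match no HBC library to the RBC library.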

Other observations

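The tests of explanations in this part were chosen after the results had been seen, whereas the gene lists and camera's test of them were planned. A few keratin and adhesion genes, picked after their values were seen and belonging to no list that was tested, are given as values. Krt7 was 27.2-fold higher in HBC libraries (49217 ± 901, SD, n = 3, against 1810), Krt8 was 5.87-fold higher (28897 ± 788 against 4924), Krt18 was 3.83-fold higher (38620 ± 915 against 10071) and Krt19 was 5.80-fold higher (38057 ± 393 against 6563). The epithelial adhesion gene Epcam was 2.2-fold higher (7025 ± 127 against 3197) and the hyaluronan receptor Cd44 was 3.70-fold higher (1977 ± 50.2 against 535). Cdh1, the epithelial cadherin, was at 4468 ± 104 and 2423.

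Xist and some Y-linked genes were likewise picked after their values were seen. Xist was at 1297 ± 109 in HBC libraries and 1563 in the RBC library (limma adjusted p = 0.138). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were listed at 0 in each HBC library and stood at 95.7, 187, 37.7 and 46.2 in the RBC library. That library thus held Xist and Y-linked transcripts together, and whether it came from animals of both sexes was not tested.

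In the RBC library, 46 of 55 tested markers of leukocytes, fibroblasts and endothelium (83.6%) were called higher than in the cultures. Over all genes tested, 5621 of 16440 were called higher in it. Members listed at 0 in a group numbered 8 of 23 leukocyte, 1 of 18 fibroblast and 3 of 14 endothelial genes. Where that group was HBC, the filter fixed the call. The summed values gave no sign of greater depth of that library, at 0.910 of the highest HBC sum. They are sums of length-scaled values and depth in reads is unknown, so this test cannot decide. The library had 2405 more genes above 0 than the HBC library with the most, which greater depth could also bring. RNA of other cell types in the sorted sample and marker expression within descendants of the Krt5-traced cells cannot be told apart, because the 83.6% is the pattern itself and there is only 1 RBC library. The most abundant of these markers in the RBC library were Lyz2 (14770) and Cd74 (1001) of leukocytes and Dcn (6902) and Sparc (1609) of fibroblasts. For endothelium they were Ramp2 (43.0) and Plvap (31.7). Most markers were far lower than the top ones of leukocytes and fibroblasts. The median tested member in the RBC library was at 48.9 for leukocytes, 37.7 for fibroblasts and 12.2 for endothelium, against 2143 for the basal list. Sparc was also at 204 ± 9.69 in HBC libraries. A sort for TdTomato should remove such cells, but the purity of the sorted sample was not tested. The corresponding share for ciliated, secretory, gland and sustentacular markers was 89.7% (61 of 68), and for these, traced descendants and untraced epithelial cells cannot be told apart, because both would bring the same transcripts and the design has no sample that separates them.

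Immediate early genes were the second pattern, with 76.0% of the tested members called higher in the RBC library. The list call was lost with an estimated correlation (camera adjusted p = 0.193, with a range of 1.13e-08 to 0.193 over the alternatives of this test). The estimate was 0.00997, close to the preset 0.01, so the loss came with the 2 degrees of freedom of that version. Scaling between libraries is argued against, since the lowest list median over 5 scalings was a log2 change of 3.89. Dissociation and sorting may have induced them, but this cannot be told apart from a difference between the tissues or from the culture, because a sort is given for the RBC sample alone.

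Interferon-response genes were the third pattern, with 19 of 25 tested members called higher in the HBC libraries, 6 not called and a list call that was lost with an estimated correlation (camera adjusted p = 0.193, with a range of 6.69e-12 to 0.193 over the alternatives of this test). Scaling is argued against, since the list median was -2.54 or lower under each of 5 scalings. A response to culture conditions, a difference between olfactory and respiratory basal cells, and the strains of the animals may each contribute and were not tested.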
